A study of Saccharomyces cerevisiae with 218 samples.

How the data were processed

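Samples were yeast derived from W303 that takes up EdU, with HA-tagged Rpb3. They comprised Input, bulk ChIP, NChAP, ChIP-NChAP and unreplicated ChIP fractions of WT, Mcm2-3A and rtt109D cells, in 10 tables. The deposited values are signal: read coverage in 50 bp bins, on the F and R strands apart, which the authors scaled so that each library and strand has its own genome mean near 1. Per the labels, CASAVA 1.7.0 was used. The letter R stands in place of values in 4.84% of bins in most tables, and those bins were left out. A few columns hold zero there instead. The deposited timing score comes from a published profile named in the file header (low = early here, from its correlation with NChAP at 18 min). Exact zeros of the score were treated as missing. One table covers only 4 chromosomes. The genome build of the tables is not stated, and gene marks on chromosome 11 are shifted against the reference annotation, so the tables' own gene and origin marks were used for positions and the reference annotation for names only. Gene values are means over the bins the tables mark for a gene, at least 4 of them, rather than over bins whose centre lies in the annotated gene, which was the plan. The deposited depth per library is unknown.

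Gene values are sums of both strands divided by the genome mean. Ratios were log2 with a pseudocount of 0.1 of the genome mean, and genes with a denominator under 0.25 were left out. Nascent values are ChIP-NChAP over NChAP, bulk values ChIP over Input, and their difference was taken within a culture. Chase libraries, which have no NChAP, used ChIP-NChAP over Input. Ratios were centred at their median over genes. Times of 20 and 25 min of one replicate number were averaged as 1 culture. Origins are the marked origins with an above-median NChAP signal at 18 min in an independent WT experiment, 135 of 270, of which 124 had values in all flanks. Windows are 1 kb with at least 10 bins. Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

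Comparisons were nascent against bulk in WT and, added later, in Mcm2-3A with the difference between genotypes, Mcm2-3A against WT on nascent DNA, in bulk Rpb3, at origins and over the time course, 25 against 20 min, 15 against 7 min of chase, and the libraries labelled rtt109D against WT and against their own bulk. Single libraries are given as values. WT and Mcm2-3A lie in different tables, and were compared because each library is scaled by itself. Genes named were, per comparison, the 10 largest increases and the 10 largest decreases past the threshold that moved the same way in every culture (5 and 5 for H3, H3K4me3 and H3K36me3), or the 5 smallest raw p where none passed. The 2 largest and 2 smallest members of each list, RTT109, MCM2 and RPB3 could be named too. One gene that met this rule is not reported here. For origins, the listed ones and the 5 largest were taken, and for windows the 5 largest each way. The 14 gene lists, the comparisons and most alternatives were chosen before the data were examined. The lists hold histone genes, histone chaperones and modifiers, G1 to S cyclins and replication, the G2 to M CLB2 cluster, M to G1 genes, ribosomal proteins, ribosome biogenesis, glycolysis, heat shock and stress, DNA damage response, galactose, phosphate starvation, pheromone response, and meiosis and sporulation.

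Alternatives were pseudocounts of 0.5 and 0.02, no filter, no centring, single times, no pairing, a replicate block, other flanks and origin sets, division by Input, and each replicate left out. The fits were tested on simulated data: of 200 genes changed by 2 on the log2 scale, 100% were recovered for nascent minus bulk Rpb3 in WT and 95% for Mcm2-3A against WT, and 47% and 8.5% of those changed by 1. No 2 libraries had identical gene values. Of the samples, 7 have no column of their own. These are repeat runs and both runs of WT replicate 2 at 25 min in the time course, whose column names neither run and was used as that replicate.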

Results

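Chromatin on newly replicated DNA was profiled in budding yeast cultures released from an alpha factor arrest in G1 into medium with EdU, a thymidine analogue that marks new DNA. NChAP (nascent chromatin avidin pulldown) isolates the EdU-labelled fragments, and ChIP-NChAP isolates them from a chromatin immunoprecipitate of Rpb3 (a subunit of RNA polymerase II), H3, H3K4me3, H3K36me3 or H3K56ac. The labels list 218 samples in 126 groups, and the tables hold 212 libraries, with 2 libraries in each of 86 groups and 1 in each of 40. Values are normalised coverage in 50 bp bins on each strand, and the mean of each library and strand over the genome lay between 0.781 and 1.23. The read depth of the libraries is unknown, so no counting interval is given. Log2 differences are given with the limma standard error (SE). The p-values rest on the spread between labelled replicates, which were 2 per group, pooled in part or in full over genes, origins or windows.

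In WT cells at 20 and 25 min, RNA polymerase II on nascent DNA differed from bulk chromatin at some genes under the main settings. Bulk chromatin also holds unreplicated DNA, per the labels 65 and 70% of the genome at 20 min and 25 and 39% at 25 min. For all targets, nascent against bulk is therefore not a comparison of matched stages of replication. Rpb3 on nascent DNA, each fraction divided by its own input, was lower than in bulk at 93 genes and higher at 38 of 2910 genes tested with limma (2 WT cultures). Genes of the G1 to S transition and of DNA replication held the largest decrease: RNR1, the large subunit of ribonucleotide reductase (YER070W, chromosome 5, 298951 to 301651), fell by 2.50 on the log2 scale (SE 0.36, adjusted p = 0.000695). In the same list fell by 1.98 CLB6, an S-phase cyclin, and fell by 1.94 RFA3, a subunit of the single-stranded DNA binding complex. Of 26 measured members of this list, 8 fell and 0 rose, with a median of -0.82, and 13 fell when adjusted over the list alone. Other decreases were at TOS6 (-2.28), ACM1 (-2.18), FAS2 (-1.81), HSL1 (-1.80) and TOS4 (-1.78). The histone chaperone gene ASF1 (-1.43), the pheromone-pathway kinase gene FUS3 (-1.39) and the replication licensing gene CDC6 (-1.10) fell as well.

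Some ribosomal protein and glycolysis genes were also lower on nascent DNA. Of 91 ribosomal protein genes, 18 fell and 0 rose, with a median of -0.71, and RPL24B (-1.91) and RPL34B (-1.80) fell most. Adjusted over the list alone, 33 of them fell. Among 15 glycolysis genes 4 fell, with a median of -0.60, and 7 fell when adjusted over the list alone. They included PDC1, pyruvate decarboxylase (-1.74, SE 0.30), and ADH1, alcohol dehydrogenase (-1.23, SE 0.30). Ribosome biogenesis genes had a median of -0.41 with 0 of 27 past the threshold, and 4 lower when adjusted over the list alone.

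The genes that rose included FIG1, a gene for mating (2.07, SE 0.32), SPG4 (2.30, SE 0.32), ANB1, a gene repressed in the presence of oxygen (1.44, SE 0.32), GAD1 (1.43) and HUG1, a gene of the DNA damage checkpoint response (1.39). Meiosis and sporulation genes, which are silent in dividing cells, had positive differences in 18 of 18 members with a median of 0.52, and 2 of them rose. These were SSP1 (1.27, SE 0.30) and SPR3 (1.23, SE 0.33), and 6 rose when adjusted over the list alone. GIP1 (1.40) and SPO23 (1.35) rose too. Histone genes were positive in 8 of 9 members with a median of 0.70. HHT1 (1.29, SE 0.32, adjusted p = 0.0225) rose, HHF1 (1.10, SE 0.36, adjusted p = 0.0723) missed the threshold, and 4 rose when adjusted over the list alone.

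Camera with a preset correlation called 6 of the 14 fixed lists in this comparison, and adjusted p = 0.376 to 0.727 with an estimated correlation. With few residual degrees of freedom, the estimated correlation does not decide whether the calls hold. The 131 calls were not stable: 45 genes passed without WT replicate 1, 32 of them among the 131, 43 genes with 25 min alone, 21 of them among the 131, 230 with a pseudocount of 0.5, 114 of them among the 131, and 0 with 20 min alone, with a pseudocount of 0.02 or without pairing the fractions of a culture. In Mcm2-3A 12 genes rose and 23 fell, and the test of the difference between the genotypes called 0 genes (77 at an unadjusted p under 0.05).

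**Figure D1:**
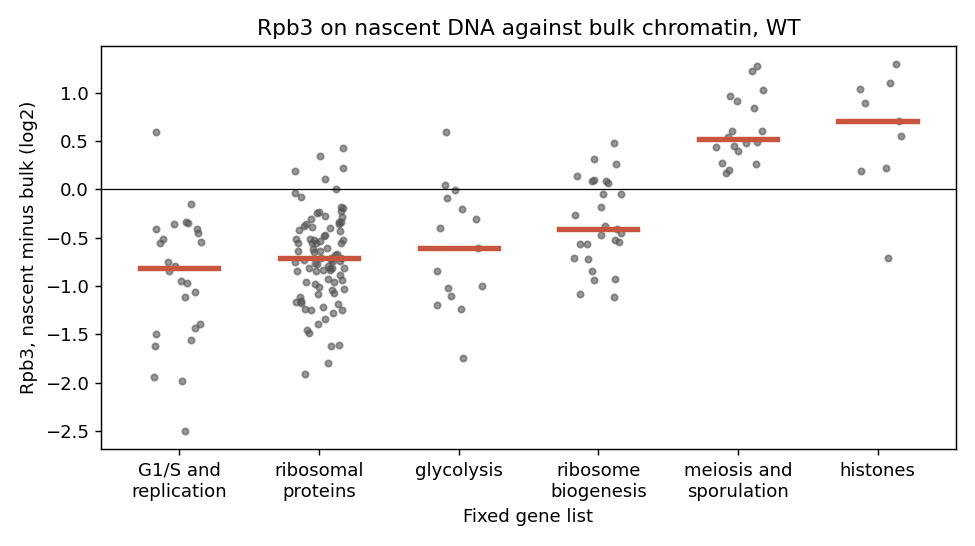
Rpb3 on nascent DNA minus bulk chromatin (log2, vertical axis) in WT for the members of 6 gene lists (horizontal axis). Each dot is a gene's estimate from 2 cultures and each bar is the median of the list, which runs from -0.82 for G1 to S and replication genes to 0.70 for histone genes.

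H3K56ac marks newly deposited H3 and had the widest redistribution of the 5 targets. In WT, 871 genes were higher on nascent DNA than in bulk and 798 lower, among 2910 tested with limma. The largest decrease was at a core histone gene: HHF1 fell by 2.59 (SE 0.18, adjusted p = 4.12e-05). HTB1 fell by 2.15 (SE 0.18) and HTB2 fell by 1.90 (SE 0.18). Of 9 histone genes, 6 fell and 0 rose, and the median was -1.84. ECM15 (-2.16), GLC8 (-2.09) and the thioredoxin gene TRX1 (-2.0) fell too. The largest increases were at PAU20 (2.18, SE 0.17), the cell wall gene DAN4 (1.95), the helicase gene SEN1 (1.94), MCM5 of the replicative helicase (1.89), MLP1 (1.79) and the clathrin gene CHC1 (1.76). MCM2 rose as well (0.79, SE 0.17).

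Members of other lists went both ways for H3K56ac. Of 26 G1 to S and replication genes, 13 rose, among them TOF1 (1.13) and RNR1 (0.93), and 7 fell, among them RFA3 (-1.57) and CLB5 (-1.30). Of 15 glycolysis genes 9 fell, such as TPI1 (-1.75) and PDC1 (-1.39), and 3 rose. Among 91 ribosomal protein genes 29 fell, such as RPL23A (-1.34), and 6 rose, such as RPL32 (1.09). In 6 galactose genes 4 rose, among them GAL7 (1.32) and GAL10 (1.28). Adjusted over the list alone, 6 histone genes, 8 G1 to S genes, 9 glycolysis genes and 20 ribosomal protein genes fell, and 13 G1 to S genes and 4 galactose genes rose. Camera with a preset correlation called the histone list (adjusted p = 0.00449) and the ribosomal protein list (adjusted p = 0.0239), but adjusted p = 0.872 for each with an estimated correlation. Across 2893 genes, Spearman's rho of the bulk H3K56ac ratio with the timing score, which is low for early genes, was -0.35 and -0.363 in the 2 WT cultures, and rho of the nascent ratio was 0.016 and 0.129. Genes are not independent replicates. The count was 964 without WT replicate 1, 1088 without WT replicate 2 and 973 with 20 min alone. In Mcm2-3A 812 genes rose and 865 fell, and the test of the difference between genotypes called 0 genes (100 at an unadjusted p under 0.05).

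For H3K4me3, a mark of active promoters, 62 genes were higher on nascent DNA in WT and 3 lower. PAU20 (2.58, SE 0.34), ANB1 (2.09, SE 0.25), API2 (1.98), the sporulation genes SPR3 (1.61) and DIT2 (1.15) and GAL7 (1.01) rose. HTB1 (-1.31, SE 0.28) and HHF1 (-0.97, SE 0.23) fell, and HHT1 was at -1.11 (SE 0.36, adjusted p = 0.136). Histone genes had a median of -0.62 with 0 of 9 positive, and 4 fell when adjusted over the list alone. Adjusted p = 0.00014 for the list with a preset correlation and adjusted p = 0.647 with an estimated correlation. These counts were not stable: 0 genes passed with a pseudocount of 0.02 or with either time alone, and more passed without centring or with no filter, as given below. They also changed when a replicate was left out. A compressed signal range in ChIP-NChAP, weighed for Rpb3 below, was not tested for H3, H3K4me3, H3K36me3 or H3K56ac.

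For H3K36me3, a mark of transcribed gene bodies, 0 genes passed in WT with limma (321 at an unadjusted p under 0.05). The smallest raw p included ANB1 (2.28), SPO19 (2.30) and MED11 (1.93), each at an adjusted p = 0.0673, and GAL7 was at 1.46. Galactose genes were positive in 6 of 6 members and meiosis genes in 13 of 18, and adjusted over the list alone 3 and 4 of them rose. Adjusted p = 0.0275 and 0.00852 with a preset correlation, and adjusted p = 0.799 for both lists with an estimated correlation. Without centring the ratios, 192 genes passed, all higher. Centring removed a median shift of 0.309 for H3K36me3 and 0.193 for H3K4me3. For H3 itself, 0 genes passed (162 at an unadjusted p under 0.05), and HSP150, a cell wall gene, was at 1.15 with an adjusted p = 0.191.

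Mcm2-3A carries changes in Mcm2, a helicase subunit that binds H3 and H4. Around origins, histone marks were shared between the F and R strands differently than in WT. Strand asymmetry is the log2 ratio of F to R coverage right of an origin minus that left of it, divided by 2, from 250 bp to 5 kb. The labels do not say which strand F and R stand for, so no sign is assigned to the leading or the lagging strand. Over 124 origins, H3K4me3 asymmetry was higher in Mcm2-3A at 122 (median difference 1.68) and H3K36me3 asymmetry at 123 (median 1.75). H3K56ac moved the opposite way, lower at 123 origins (median -1.07). Total H3 was higher at 114 origins (median 0.41), which became 74 without either Mcm2-3A replicate.

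Each culture showed this. For H3K4me3, H3K36me3 and H3K56ac the fit used a single variance for all origins (248 degrees of freedom), and origins of a culture are not independent. The counts of origins therefore restate a difference between 2 cultures per genotype, rather than separate findings at each origin. Mean H3K4me3 asymmetry was 1.94 and 1.53 in the Mcm2-3A cultures (1.73 ± 0.286, SD, n = 2) against 0.101 ± 0.033 (SD, n = 2) in WT. Mean H3K56ac asymmetry was -1.03 ± 0.15 (SD, n = 2) against 0.018 ± 0.026 (SD, n = 2) in WT. At the early origin ARS305 (chromosome 3, 39201 to 39751), the difference was 1.7 for H3K4me3 (SE 0.236), 1.62 for H3K36me3 (SE 0.157) and -1.14 for H3K56ac (SE 0.128). At ARS607 (chromosome 6, 199401 to 199501) the differences were 1.68, 1.64 and -1.19. All 7 measured origins listed as early firing moved with each of the 3 marks and with H3, also when adjusted over the list alone. The differences reached 2.14 at ARS731 for H3K4me3, 2.11 at ARS1621 for H3K36me3 and -1.40 at ARS406 for H3K56ac.

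NChAP without immunoprecipitation and Rpb3 had 0 of 124 origins past the threshold with limma (12 and 31 at an unadjusted p under 0.05), with medians of -0.07 and -0.23 and positive differences at 20 and 12 origins. Mean Rpb3 asymmetry was -0.067 and -0.145 in the Mcm2-3A cultures against 0.136 and 0.096 in WT. WT and Mcm2-3A lie in different tables. In WT the asymmetries were small: the medians were 0.05 for NChAP, 0.11 for Rpb3, 0.04 for H3, 0.11 for H3K4me3, 0.10 for H3K36me3 and 0.02 for H3K56ac. The counts past the threshold in WT were 15 for NChAP, 34 for H3, 4 for H3K4me3, 21 for H3K36me3, 2 for H3K56ac and 0 for Rpb3 (28 at an unadjusted p under 0.05), and most changed with the flank or with a replicate left out. With the NChAP asymmetry subtracted, 5 origins passed for H3, 0 for H3K4me3, 2 for H3K36me3 and 0 for H3K56ac. Across origins the asymmetries of these marks in WT correlated with that of NChAP, at 0.652 and 0.893 in the 2 cultures for H3, 0.604 and 0.836 for H3K4me3, 0.355 and 0.796 for H3K36me3 and 0.637 and 0.867 for H3K56ac. Mean asymmetry differed between the WT cultures for H3 (0.091 and 0.003) and H3K56ac (0.036 and 0). The largest mean NChAP asymmetries in WT were at ARS214 (0.35, SE 0.061, with 0.166 and 0.543 in the cultures), ARS216 (0.32, with 0.324 and 0.320) and ARS202 (0.26, with 0.138 and 0.390).

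**Figure D2:**
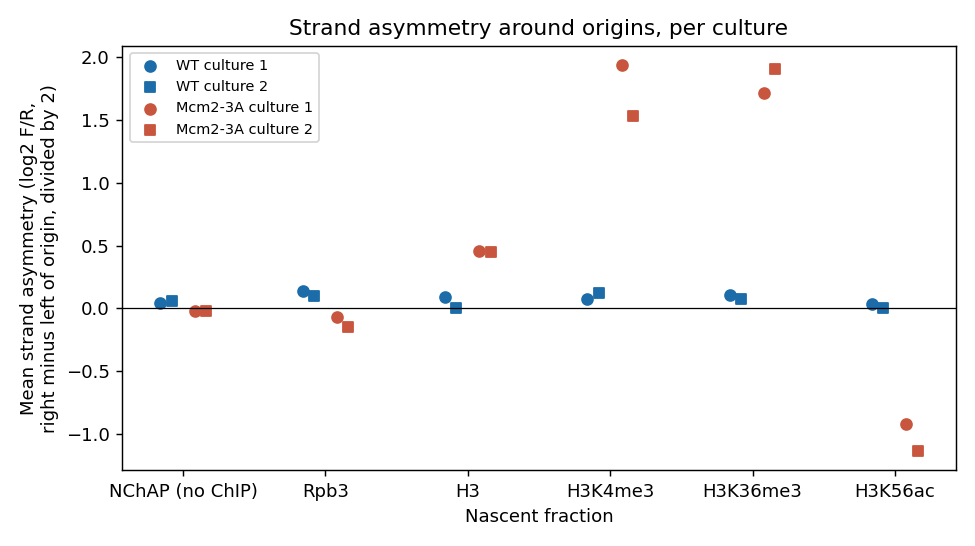
Mean strand asymmetry over 124 origins (vertical axis, log2 units) for each nascent fraction (horizontal axis), with 1 point per culture. H3K4me3 and H3K36me3 lie between 1.53 and 1.94 in the Mcm2-3A cultures, H3K56ac lies at -0.92 and -1.14, and the WT cultures stay between 0 and 0.14.

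Summed over both strands, only H3K4me3 of the 4 histone targets had genes past the threshold between Mcm2-3A and WT on nascent DNA. For H3K4me3, 19 genes were higher and 50 lower in Mcm2-3A among 2911 tested with limma. SBH2, a subunit of the protein translocation channel (-2.92, SE 0.42), SDH6 (-2.26, SE 0.38), LSO2 (-2.17, SE 0.30), TOS6 (-2.07) and ADF1 (-2.01) fell, while VRL1 (1.40) and RRT7 (1.37) rose. The count was 1 without WT replicate 1, 216 without WT replicate 2, 44 and 26 without Mcm2-3A replicates 1 and 2, and 0 over the first 500 bp of genes. For H3, H3K36me3 and H3K56ac, 0 genes passed (248, 198 and 152 at an unadjusted p under 0.05). HHF1 (-1.57) and LSO2 (-1.74) for H3, and IGD1 (-0.95) and CYC1 (-0.86) for H3K56ac, had among the smallest raw p and missed the threshold. Ribosomal protein genes were positive for H3 in 66 of 91 members with a median of 0.31, called with a preset correlation (adjusted p = 9.12e-05), with adjusted p = 0.88 with an estimated correlation.

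RNA polymerase II on nascent DNA was lower in Mcm2-3A at 1 gene, NBP1 (YLR457C, -2.40, SE 0.48), and at 0 genes with either other pseudocount, with no filter, with no centring or with either time alone, but at 54 genes without WT replicate 2. Members of 3 lists leaned together: 4 of 26 G1 to S genes (median -0.32), 13 of 15 glycolysis genes (median 0.35) and 0 of 9 histone genes (median -0.45) were positive, with 0 members past the threshold. Camera called these 3 lists with a preset correlation, with adjusted p = 0.92 for each with an estimated correlation. In bulk chromatin 0 of 5680 genes passed (213 at an unadjusted p under 0.05). The gene with the smallest raw p was MCM2 itself, at 0.94 (SE 0.11, adjusted p = 0.988), followed by RPS4A at -0.62. Per the labels, the Mcm2-3A cultures had replicated more than the WT cultures of the same number, with 52 and 67% of the genome unreplicated against 65 and 70% at 20 min and 20 and 34% against 25 and 39% at 25 min, and the comparisons of the genotypes were not matched for this. In bulk, 34 of 36 G1 to S genes and 132 of 135 ribosomal protein genes had negative differences, with medians of -0.28 and -0.17, and 14 of 16 glycolysis genes positive ones. Camera called these lists with a preset correlation, with adjusted p = 0.545 for each with an estimated correlation, and 0 members passed alone. Between 20 and 25 min in WT, Rpb3 on nascent DNA passed at 0 genes with limma (225 at an unadjusted p under 0.05). On simulated data this comparison recovered 1% of genes changed by 1 on the log2 scale and 73% of those changed by 2. The 0 calls therefore do not show that changes of this size were absent. POL30, the sliding clamp gene, was at -2.56 (SE 0.65, adjusted p = 0.476). G1 to S genes had a median of -0.56, called with a preset correlation (adjusted p = 5.49e-05), with adjusted p = 0.863 with an estimated correlation.

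NChAP coverage was highest in early windows at 25 min in both genotypes, and this excess shrank later. Over 1 kb windows, the median of the early quartile minus that of the late quartile was 3.82 and 4.05 in the WT cultures at 25 min. It was 3.80 and 3.85 in Mcm2-3A. By 48 min it was -0.28 and -0.30 in WT and 0.32 and -0.17 in Mcm2-3A, and at 55 min it was 0.195 and -0.131 in WT and 0.368 and -0.289 in Mcm2-3A. Of 11419 windows, 0 passed with limma at 18, 25, 40, 48 and 55 min (414, 100, 130, 317 and 111 at an unadjusted p under 0.05). The WT replicates correlated at 0.87, 0.988, 0.43, 0.867 and 0.352 at these times. On data simulated for 32 min, the fit recovered 9.5% of windows changed by 1 on the log2 scale and 98.5% of those changed by 2. The 0 calls therefore do not show that changes of 1 were absent. At 32 min 24 windows were higher in Mcm2-3A and 902 lower, 586 of the latter in the latest quartile. However, 0 windows passed without centring, 1 with a pseudocount of 0.5 and 151 when divided by Input. These p-values rest on a spread shared by all times and both genotypes, rather than on the spread at 32 min. In the latest quartile the median at 32 min was -1.615 and -0.929 in the WT cultures and -1.944 and -1.757 in Mcm2-3A. The largest increase was on chromosome 12 at 15001 to 16000 (1.77, SE 0.28) and the largest decrease on chromosome 2 at 564001 to 565000 (-1.74, SE 0.35). The WT replicates at 32 min correlated at 0.734 across windows, and 0 windows passed without either Mcm2-3A replicate and 7030 without WT replicate 2.

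**Figure D3:**
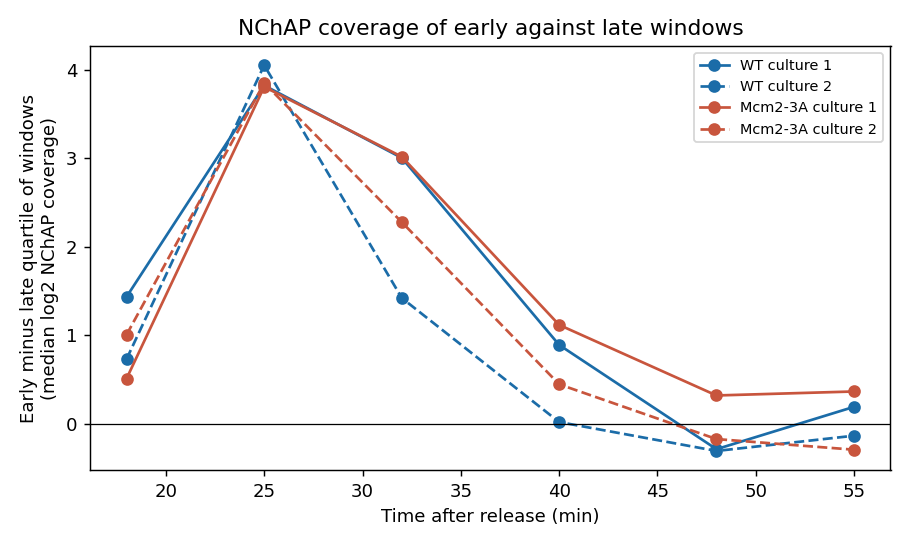
Median log2 NChAP coverage of the early minus the late quartile of 1 kb windows (vertical axis) against minutes after release (horizontal axis), with 1 line per culture. All 4 cultures peak at 25 min, between 3.80 and 4.05, and the WT cultures part at 32 min, at 3.00 and 1.42.

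In mid-log cells given an EdU pulse and a chase, Rpb3 on nascent DNA was compared at 15 min minus 7 min. These libraries have no NChAP, so the ratio to Input also holds the distribution of labelled DNA. Labelled cells advance through the cell cycle during the chase, which cannot be told apart here from a return of polymerase with time. With limma, 0 of 5684 genes passed (301 at an unadjusted p under 0.05). TMA10 (1.96, SE 0.31), the hexose transporter gene HXT6 (1.57) and RNR1 (-1.89, SE 0.38) had among the smallest raw p. Mitotic genes of the CLB2 cluster were positive in 15 of 16 members with a median of 0.50, CLB2 itself at 1.10, and 3 rose when adjusted over the list alone. G1 to S genes were negative in 29 of 36 with a median of -0.28. Camera called both lists with a preset correlation (adjusted p = 7.38e-08 and 5.31e-05), and adjusted p = 0.343 and 0.454 with an estimated correlation.

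The libraries labelled rtt109D come from a strain lacking the H3K56 acetyltransferase per the labels, but 2 of the 8 carry RTT109 coverage at or above the WT level, so the identity of their cells is open. One of these, Rpb3 ChIP-NChAP of replicate 1, correlated at 0.858 with its NChAP and at 0.304 with its Rpb3 ChIP across genes, against 0.812 and 0.638 in replicate 2. Compared at 10% unreplicated genome, which is 25 min in these libraries and 32 min in WT, Rpb3 on nascent DNA in these libraries minus WT passed at 0 of 4751 genes with limma (219 at an unadjusted p under 0.05). CDC42 (-3.37, SE 0.64) had the smallest raw p. Ribosomal protein genes were negative in 124 of 126 members with a median of -1.24, which was -2.08 in replicate 1 and -0.36 in replicate 2. Glycolysis genes were negative in 14 of 16 with a median of -1.82 (-2.62 and -1.26 in the replicates), such as TDH3 (-2.94, SE 0.73), with 10 lower when adjusted over the list alone. Centring removed a shift of 0.141, and adjusted p = 0.778 for both lists with an estimated correlation. Within these libraries, nascent minus bulk Rpb3 passed at 0 of 4564 genes (323 at an unadjusted p under 0.05), with TEF2 (-3.25, SE 0.73) and RPL29 (-3.15, SE 0.73) at an adjusted p = 0.05001. TEF2 was at -5.10 in replicate 1 and -1.39 in replicate 2, and RPL29 at -5.51 and -0.79. Histone genes had a median of -1.68 there, negative in 10 of 10, but the median was -3.49 in replicate 1 and -0.14 in replicate 2, and 5 were lower when adjusted over the list alone (adjusted p = 3.88e-09 for the list with a preset correlation, adjusted p = 0.812 with an estimated correlation).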

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

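The tests of exchanged strand columns, of the nascent DNA isolation and of the whole Mcm2-3A table were chosen after the result was seen, and so were the test of the difference between genotypes and the tests of a compressed signal range for the meiosis, histone and ribosome biogenesis lists.

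H3K4me3 on nascent DNA against bulk differed between the genotypes at 2 genes by a test of the difference itself. Mcm2-3A minus WT was -2.76 (SE 0.43, adjusted p = 0.0224) at SBH2 and -2.10 (SE 0.33, adjusted p = 0.0224) at LSO2 with limma. Both Mcm2-3A cultures lay below both WT cultures at each gene. SBH2 was at 1.71 and 0.44 in the WT cultures and at -1.20 and -2.16 in Mcm2-3A. Both genes are short, marked from 194301 to 194551 on chromosome 5 (SBH2) and from 836401 to 836701 on chromosome 7 (LSO2). No alternative settings are given for this test. At LSO2, H3 on nascent DNA was also lower in Mcm2-3A (-1.74, which missed the threshold), and H3K4me3 was not divided by H3. RTT109 is deleted in rtt109D per the labels, yet its relative coverage was 1.17 in Input replicate 1 and 2.12 in ChIP-NChAP replicate 1. It was 0.0519 in Input replicate 2, 0.0751 in ChIP-NChAP replicate 2, 0.116 and 0.0656 in ChIP and 0.298 and 0.352 in NChAP. Over 29 WT Inputs it ran from 0.889 to 1.62.

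Strand asymmetry of histone marks around origins in Mcm2-3A was large for H3K4me3, H3K36me3 and H3K56ac. Strand columns exchanged at both times of a culture would leave its size unchanged, and the median absolute H3K4me3 asymmetry was 10.6 times that of WT. An exchange at only 1 of the times averaged in a culture could cancel the asymmetry, so the test does not cover it. The other marks were not tested for an exchange. A strand bias of the nascent DNA isolation would appear in NChAP, where the median difference was -0.068. A strand bias of the whole Mcm2-3A table that is equal on both sides of an origin cancels in right minus left. The values therefore do not test it. A bias that differs between the sides would move all fractions alike. H3K56ac went the other way (-1.071), which an exchange of its columns could also give. NChAP of the same table moved by only -0.068. A mapping or sequence bias near origins would appear in bulk H3K4me3, where the difference was -0.0194. The tables argue against exchanged columns, a bias of the nascent DNA isolation and a mapping or sequence bias, in the form tested. Genotype goes with table, and other differences between the tables stay open. A hypothesis is that the mutation may alter how old and new histones are shared between the sister strands. This was not tested. Deciding it needs both genotypes in 1 experiment, with the leading and lagging strands identified.

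H3K56ac on nascent DNA against bulk moved at 1669 genes in WT. Calls were not confined to genes with weak nascent coverage, since 61.1% of genes with a mean NChAP of at least 1 were called, against 57.4% of all. This does not exclude an effect of weak coverage of late genes. Centring at the median over genes would shift well-covered genes the opposite way. If bulk H3K56ac followed the order of replication, its ratio would correlate with the timing score. The correlation was -0.358 for the bulk ratio, 0.082 for the nascent ratio and 0.389 for their difference. Whether this produces the pattern cannot be told apart, because the bulk correlation lies between the values that the explanation needs and forbids, as set before the test. A compressed signal range in ChIP-NChAP was not tested for H3K56ac, and no biological explanation was tested.

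Rpb3 on nascent DNA against bulk fell with the level of Rpb3 in an independent bulk experiment (rho -0.454 across 2910 genes). A compressed signal range in ChIP-NChAP could account for the fall of ribosomal protein genes, whose median residual after that trend was -0.008 against a difference of -0.71. It also goes with that of glycolysis genes, -0.289 against -0.602, and of ribosome biogenesis genes, -0.046 against -0.41, and with the rise of meiosis and sporulation genes, 0.23 against 0.518. The tables argue against it for the rise of histone genes, whose residual of 1.788 exceeds their difference of 0.704. For G1 to S and replication genes the residual was -0.516 against -0.817, and this part cannot be told apart, because the residual lies between the values the explanation needs and forbids. A biological explanation was not tested.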

How the results depend on the processing

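Under alternatives, 186 counts stayed within 1.5 times the reported count and 128 did not. Genes were named for the same direction in every culture, a small raw p or an extreme difference, which makes a kept sign likely. The 897 values of named genes under alternatives kept their sign, with 0 reversed. Of these, 659 stayed on their side of the threshold, 202 were no longer past it and 36 came past it. The crossed replicate blocks were chosen after seeing the data, and the cause of the changes below was not tested. Leaving out a replicate assumes that the lone culture varies like the others. For nascent against bulk in the libraries labelled rtt109D it leaves no residual degrees of freedom and was not run. With an estimated correlation, camera called 0 lists in every gene comparison that had calls. Its residual degrees of freedom are few with 2 cultures per group, so this does not decide whether the calls hold. Read depth is unknown, so its effect on these counts is not known.

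Nascent against bulk in WT gave, for Rpb3 (131 genes), 230 with a pseudocount of 0.5, 0 with 0.02, 250 with no filter, 73 not centred, 0 with no replicate block, 43 with 25 min only, 0 with 20 min only, and 45 to 219 with a replicate left out. For H3 (0 genes) it gave 13 with no filter and 0 to 30 with a replicate left out. For H3K4me3 (65 genes) it gave 106 with a pseudocount of 0.5, 0 with 0.02, 380 with no filter, 207 not centred, 32 with no replicate block, 0 with either time only, and 0 to 175 with a replicate left out. For H3K36me3 (0 genes) it gave 2 with a pseudocount of 0.5, 532 with no filter, 192 not centred, 103 with no replicate block, 1 with 25 min only, and 0 to 2 with a replicate left out. For H3K56ac (1669 genes) it gave 3344 with no filter, which tests more genes, 973 with 20 min only, and 964 to 1638 with a replicate left out.

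Mcm2-3A against WT on nascent DNA gave, for Rpb3 (1 gene), 0 with pseudocounts of 0.5 and 0.02, no filter, not centred, a replicate block, 25 min only and 20 min only, and 0 to 54 with a replicate left out. For H3 (0 genes) a left-out replicate gave 0 to 35. For H3K4me3 (69 genes) it gave 120 with a pseudocount of 0.5, 0 with 0.02, 27 with no filter, 106 with a replicate block, 2 with 25 min only, 0 with 20 min only, 0 over the first 500 bp, and 1 to 216 with a replicate left out. For H3K36me3 (0 genes) it gave 2 not centred. Bulk Rpb3 (0 genes) gave 9 with the crossed replicate block and 0 to 49 with a replicate left out. For 25 against 20 min (0 genes), a pseudocount of 0.5 gave 2, no filter gave 2, and a left-out replicate gave 0 to 94. For the libraries labelled rtt109D against WT (0 genes), a replicate block gave 10 and a left-out replicate 0 to 6. Against their own bulk (0 genes), a pseudocount of 0.02 gave 13 and no filter gave 4.

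The strand asymmetries of Mcm2-3A minus WT kept their counts under the flanks and blocks run for H3K4me3 (122 to 124 with a replicate left out), H3K36me3 and H3K56ac (122 to 123 each). H3 (114 origins) fell to 74 without either Mcm2-3A replicate, with 113 as the highest. Rpb3 (0 origins) gave 3 with a 10 kb flank, 12 with the crossed replicate block and 0 to 3 with a replicate left out. In WT, NChAP (15 origins) gave 0 with a 2 kb flank, 9 with 10 kb, 0 with all annotated origins and 0 to 27 with a replicate left out. Rpb3 (0) gave 18 with 10 kb and 0 to 8 with a replicate left out. H3 (34) gave 67 with 2 kb, 18 with all annotated origins and 5 minus the NChAP asymmetry. H3K4me3 (4) gave 9 with 2 kb, 1 with 10 kb, 2 with all annotated origins, 0 minus NChAP and 0 to 65 with a replicate left out. H3K36me3 (21) gave 9 with 2 kb, 2 minus NChAP and 1 to 5 with a replicate left out. H3K56ac (2) gave 12 with 2 kb, 4 with 10 kb, 8 with all annotated origins, 0 minus NChAP and 0 to 18 with a replicate left out. Medians of the asymmetry mostly stayed within the spread of replicates, which is wide in WT for H3 (0.0442, with -0.0276 to 0.1065 with a replicate left out) and H3K56ac (0.0194, with -0.0003 to 0.04). In WT those that did not were NChAP (0.0488), at 0.0354 with 2 kb, 0.0368 with all annotated origins and 0.0488 to 0.0609 with a replicate left out, and Rpb3 (0.114), at 0.0715 minus NChAP. H3K4me3 (0.114) was at 0.0844 with 2 kb, 0.0734 with all annotated origins and 0.0425 minus NChAP. H3K36me3 (0.102) was at 0.0438 with 2 kb, 0.0824 with 10 kb, 0.0602 with all annotated origins, 0.0405 minus NChAP and 0.0718 to 0.102 with a replicate left out, and H3K56ac (0.0194) was at -0.0308 minus NChAP. For Mcm2-3A minus WT, NChAP (-0.068) was at -0.0871 with 2 kb and -0.0811 to -0.0587 with a replicate left out.

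In the time course, the 926 windows at 32 min became 151 divided by Input, 1 with a pseudocount of 0.5, 0 not centred and 0 to 7030 with a replicate left out, and the 0 windows at 55 min became 0 to 1. The labels do not say that replicate numbers pair the cultures, but at 20 and 25 min replicate 1 had replicated more than replicate 2 in both genotypes, so the number goes with the stage of S phase. The deviations of cultures with the same number correlated positively at origins for NChAP (0.418) and H3K36me3 (0.448) and in the time course at 25 min (0.483), 32 min (0.291), 40 min (0.691) and 55 min (0.357), so that these cultures deviated together there. With a replicate block, 0 origins passed for NChAP and 123 for H3K36me3, and 1068 windows passed at 32 min and 0 at the other times. The correlation was -0.175 for bulk Rpb3, -0.102 for H3 on nascent DNA, -0.233 for Rpb3 at origins and -0.137 at 18 min, and the crossed block was run for these 4, with 0 calls for H3 and at 18 min. The other comparisons lay between -0.09 and 0.09.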

Other observations

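Single libraries showed histone genes at the top of Rpb3 on nascent DNA. In early S phase with 54% of the genome unreplicated, the log2 ratio of ChIP-NChAP to NChAP was 6.49 at HTA1, 5.80 at HHT1, 5.51 at HTB1 and 5.48 at HHF1. In unreplicated chromatin of the same culture the highest values were 4.78 at CCW12, a cell wall gene, and 4.62 at HHF2. In the experiment with 21% unreplicated genome, HTA1 was at 5.89 on nascent DNA and at 4.65 in bulk. In the table that covers 4 chromosomes, HHT1 was highest at 20 min (4.38) and at 26 min (6.72). At 24 min the highest were RPS29B (2.95) and RPL31A (2.73), and the mating gene FUS1 was among the lowest (-3.15). The relative coverage of HHT1 in NChAP was 32.9 at 24 min, against 8.61 at 20 min and 2.45 at 26 min. Its relative coverage in Rpb3 ChIP-NChAP was 105 at 24 min. The 24 min NChAP library is the denominator of the 24 min ratios. A mix-up of it was not tested, so its identity and the ranking at 24 min are in doubt. The same holds for H3K56ac on nascent DNA at 24 min in that table, highest at RPS29B (3.18) and lowest at HHF1 (-3.81).

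H3K56ac on nascent DNA at 24 min, as a single library of the experiment that also holds G1 and 35 min, was highest at MRP17 (2.98) and COX9 (2.34), genes for mitochondrial proteins, and lowest at MAL32 (-2.50). In bulk of the same experiment it was lowest at YLR111W (-2.98) and then CHA1 (-2.40) in G1, and lowest at CHA1 (-2.80) at 24 min. HHF1 had the highest bulk value in G1 (2.69).

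Of the fixed lists not described so far, in WT nascent minus bulk Rpb3, medians were 0.29 for the G2 to M CLB2 cluster, 0.27 for galactose, -0.07 for heat shock and stress, 0.04 for phosphate starvation, 0.18 for pheromone response, 0.005 for M to G1 genes, 0.22 for DNA damage response and -0.33 for histone chaperones and modifiers. Camera called none of these 8, with adjusted p from 0.15 to 0.632.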
